A study of Arabidopsis thaliana and Zea mays with 936 samples.

How the data were processed

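Affinity-tagged transcription factors (Halo or GST) were expressed in wheat germ extract or in E. coli, bound to resin and mixed with adapter-ligated fragments of naked leaf DNA, per the labels' protocols. The eluted fragments were amplified and sequenced. Reads were aligned with Bowtie2 2.0.0 to TAIR10, per the submitters' processing notes. The peak caller's version and settings and the maize build are not given in the sources used here.

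Each list holds events as intervals of 201 bp. The centre of the interval was taken as the site. The deposited signal per event is its strength, which ranked peaks within a list only, and the deposited −log10 of the q-value runs from 2 upwards. Both are the authors' own values. Of the 874 lists, 814 come from single libraries and 60 from 2 libraries each, pooled by the authors, so no list per replicate was compared. The labels do not say that repeat libraries came from separate plants. The p-values of mean differences rest on the spread over factors, those of classes on families, and those of gene lists, own genes, factor genes and sharing on random genes or exchanged labels. None measures the spread over repeats of a factor. The 2 control samples have no list, so no background list was subtracted.

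Groups were taken from the labels' protein family, protein and DNA source. The titles of 16, 13 and 3 native libraries name their DNA as col100, col200 or 100ng20cy, which the labels do not explain. They were counted as native by the DNA source label and entered 31 native lists, 19 of them pooled. Planned tests, gene lists, core motifs, alternatives and the rule for named genes were fixed before the data were examined. Added afterwards were the shares of variance between families, the CG classes set against retention, the reverse control, rank matching, the restriction by list length, the tests of recurrent sites and some alternatives. The rule named, in each family of 6 or more pairs, the factors with the highest and lowest ratio among pairs with 500 or more peaks in the longer list, the 5 longest and 3 shortest native lists, the 4 genes bound by most factors in each gene list, the 10 most bound genes, and ABI5, GBF3, MP and ZmARF5.

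Some planned features changed because of the reference at hand, a RefSeq gene table of TAIR10.1 without strand. The target window became 1000 bp outside either end of a gene to 200 bp inside it, and the promoter class became the flank of 1000 bp on both sides. Matching of factor genes used the summed distance to both neighbours. Tests of a central CG, of core motifs at peak centres and of TGTC pair spacing need genome sequence and were not run, nor was an alternative with transposable elements. The nuclear chromosomes of TAIR10 and TAIR10.1 are held to be the same, and only peak coordinates are printed. In a check, the gene table was shifted by up to 5000 bp in steps of 250 bp in 26 segments of 5 Mb. The density of peaks at gene ends was highest within 250 bp of no shift in 19 segments, and within 500 bp, a bound set after this was seen, in 25. A second check assumed that peaks avoid gene bodies. It found the lowest share inside genes within 250 bp of no shift in 0 of 26 segments, so that assumption did not hold and the check said nothing of the fit. Gene assignments rest on the first check.

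Gene-poor windows were 100-kb windows with under 25% of bases in the 27444 protein-coding genes, 186 of 1193 windows. A site was retained when a peak centre of the other list lay within 100 bp. Retention used pairs whose amplified list is labelled with binding sites and that had 20 or more gene-poor peaks among the 1000 strongest. Means over factors were tested by flipping signs, exactly up to 16 values and otherwise with 100000 draws. Class differences over families used exact permutation. Gene lists, own genes, factor genes and sharing used 10000 draws. All tests were two-sided, adjusted values are Benjamini-Hochberg, and the threshold was 0.05. Of 24 gene lists, 22 had a factor with a full native list. The aluminium list had one only on amplified DNA, and the iron list had none, so it was not tested.

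Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The statistics were tested on simulated data without an effect. The sign-flip test called 6.33% of 300 data sets of 20 values and 4.33% of 300 of 8 values, and the family and gene-list permutations called 7.00% of 200 and 7.00% of 100. Planted sites were recovered in 100.0% of 600 cases. Alternatives varied the matching window, the number of top peaks, the gene-poor definition, the lists entering, the target window and the matching. Others were added after the data were seen.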

Results

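DNA affinity purification sequencing (DAP-seq) records where a transcription factor made outside the plant binds naked genomic DNA fragments. Tagged factors, most of them translated in wheat germ extract, were immobilised and mixed with DNA of young leaves of the Arabidopsis accession Col-0. The DNA was either native, with its methylation, or PCR-amplified, which does not carry the plant's methylation. The series held 936 samples, 2 of them controls without a peak list, and gave 874 peak lists from 54 protein families. Of these lists, 530 were on native Col-0 DNA, 343 on amplified Col-0 DNA and 1 on maize DNA. Each factor had 1 list per DNA, and 60 of the lists pooled 2 libraries. Spread is therefore given over factors, not over repeats of a factor, and factors of a family are related proteins. No read totals were used, so sequencing depth behind each list is unknown here.

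List length varied widely between factors on native DNA. The median list held 2410 peaks, and the quartiles were 576.5 and 7917. The longest lists were those of At3g24120 (G2like, 33768 peaks), AT5G02460 (C2C2dof, 30519), At5g62940 (C2C2dof, 29881), EPR1 (MYBrelated, 29110) and ATHB23 (ZFHD, 27922). The shortest were those of WRKY46 (26 peaks), bHLH69 (41) and E2FC (45). The labels divide the lists into those with motif and binding sites and those with a motif alone, and a factor can carry a different label on each DNA. Lists of the first kind were longer by a mean of 3.93 on the log2 scale (12.29 ± 1.504, SD, n = 350, against 8.36 ± 1.31, n = 180; two-sided permutation p = 1e-05, the smallest the draws can give). The same difference on amplified DNA was 3.54 (n = 219 and 124, permutation p = 1e-05). The labels were given to these same data by whether binding sites are reported. The difference therefore describes the labels and is not an independent result.

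The first comparison asked whether a factor found more or fewer sites on native than on amplified DNA. Individual lists differed far in both directions. MYB77 had 27263 peaks on native and 140 on amplified DNA, a log2 ratio of 7.61, and WRKY28 had 13501 and 150, a log2 ratio of 6.49. DOF4.3 had 87 and 19070, a log2 ratio of -7.78, and At3g12730 of the G2like family had 134 and 10750, a log2 ratio of -6.33. The shorter list of each of these 4 factors carries the motif-alone label, so the ratio cannot be assigned to the DNA alone. Only factors with a list on both DNAs entered, while 530 lists were native and 343 amplified. Whether factors without an amplified list were tried on that DNA is not known here. Over 338 factors the mean log2 ratio was -0.28 ± 2.36 (SD), with 190 factors below 0 and 148 above (sign-flip permutation p = 0.0267). Among the 181 factors with full lists on both DNAs it was -0.51 ± 1.36. That choice selects on list length, the outcome itself, and unequally, since the shortest full list held 202 peaks on native and 1171 on amplified DNA, so no call is drawn from it. Among pairs of single libraries with replicate letter a on both DNAs it was -0.44 (n = 260, permutation p = 0.00416). Without lists whose titles name the native DNA otherwise it was -0.41 (n = 317, permutation p = 0.00201).

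Most of the spread lay within families, and family membership took 7.56% of the variance of the ratio (n = 291 factors, permutation p = 0.107). Family means ran from -1.99 ± 2.44 in Trihelix (n = 8) and -1.98 ± 1.95 in C2H2 (n = 11) to 0.57 ± 1.68 in NAC (n = 37) and 0.66 ± 1.73 in HB (n = 6). None of the 16 families with 6 or more factors passed adjustment, and the lowest adjusted value was 0.141 for C2H2 (exact sign-flip permutation test with Benjamini-Hochberg adjustment; unadjusted p = 0.00879, lower on native DNA in 9 of 11 factors). NAC was higher on native DNA in 22 of 37 factors (unadjusted permutation p = 0.0448, adjusted 0.358).

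The factors at the ends of each family showed the same breadth. Of the 32 factors named by this rule, 24 had a shorter list labelled with a motif alone, and 8 had full lists on both DNAs. In AP2EREBP, the ethylene response factor family, the log2 ratio ran from -4.48 for AT3G16280 to 5.69 for At4g16750. In C2C2dof it reached 4.93 for DOF4.5, in G2like 6.24 for At2g03500, and in C2H2 it ran from -5.31 for IDD5 to 1.25 for NUC. HB factors ran from -0.95 for ATHB21 to 3.97 for ANL2, and Homeobox factors from -4.46 for WUS1 to 4.16 for ATHB13. Heat shock factors ran from -3.11 for HSFB3 to 1.53 for HSFA6B, and LOBAS2 factors from -3.19 for ASL18 to 0.87 for LBD2. The lowest MYB value was -5.06 for MYB116. MYBrelated factors ran from -4.98 for AT3G10580 to 4.66 for TBP3, and NAC factors from -5.20 for SND2 to 3.24 for ANAC013. TCP factors ran from -3.42 for TCP16 to 5.54 for TCP24, and Trihelix factors from -5.52 for AT5G47660 to 0.32 for AT5G05550. The lowest WRKY value was -4.18 for WRKY6. In bHLH the range was -3.07 for bHLH10 to 3.70 for bHLH122, and in bZIP -2.82 for TGA10 to 3.01 for GBF6. The overall call was lost with the stricter q-value (mean -0.05, permutation p = 0.705, n = 338), with the mean of 26 family means (-0.24, permutation p = 0.46), and when AP2EREBP, C2H2, MYB or Trihelix was left out (permutation p from 0.0616 to 0.0912).

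**Figure D1:**
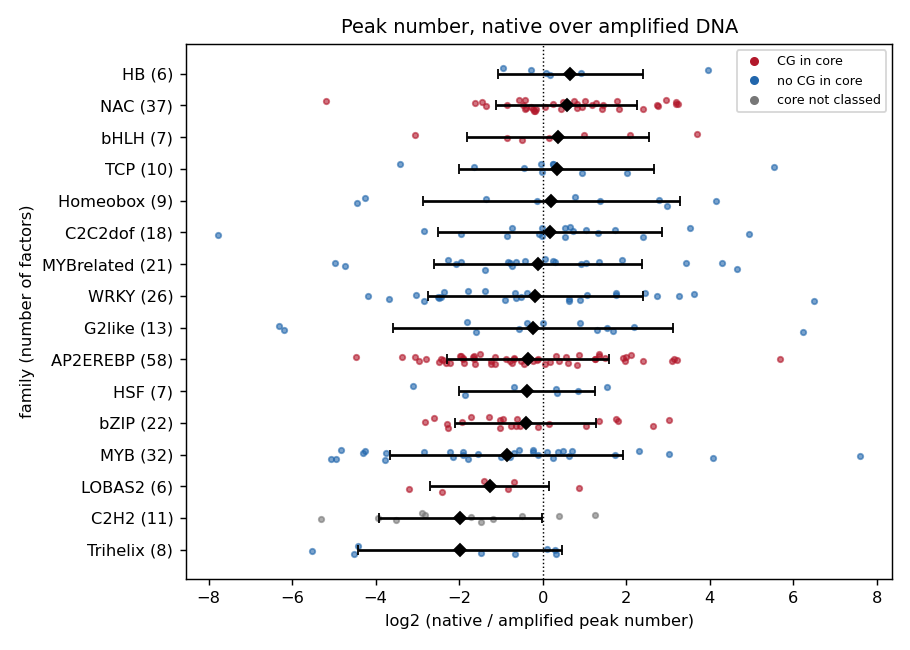
Log2 ratio of peak number on native over amplified DNA (x axis) for each factor (points) of the families with 6 or more factors (y axis, number of factors in brackets); diamonds and bars are the family mean and SD, and colours mark whether the family's textbook core motif holds a CG. Points of most families lie on both sides of 0, from -7.78 for DOF4.3 to 7.61 for MYB77.

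The second comparison asked whether sites found on amplified DNA were also found on native DNA, and whether this depended on where they lay. Sites in gene-poor windows were found again less often than sites in gene-rich windows. Of the 1000 strongest amplified-DNA peaks of a factor, 62.1% ± 30.98 (SD, n = 216 factors) of those in gene-poor windows had a native peak within 100 bp, against 77.2% ± 29.3 of those in gene-rich windows. The difference was -15.1 ± 18.1 percentage points and was below 0 in 173 of 216 factors (sign-flip permutation p = 1e-05, the smallest the draws can give).

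Families differed in the size of this loss. AP2EREBP factors kept 39.9% of gene-poor and 75.2% of gene-rich sites, a difference of -35.3 ± 17.3 points, below 0 in 34 of 35 factors (permutation test, adjusted p = 0.0001). bZIP factors kept 56.7% and 84.8%, a difference of -28.1 ± 12.9 points, below 0 in 15 of 15 (exact sign-flip permutation test, adjusted p = 0.000233). WRKY (-15.9 ± 12.4, n = 15), MYB (-13.8 ± 16.5, n = 20), NAC (-10.4 ± 12.8, n = 29) and G2like (-3.75 ± 4.92, n = 11) also passed adjustment, with permutation p-values of 0.000305, 0.00242, 0.000233 and 0.013. C2C2dof (-3.65 ± 9.03, n = 15), C2H2 (-9.10 ± 15.5, n = 8), Trihelix (-11.4 ± 26.9, n = 7) and MYBrelated (1.39 ± 7.55, n = 16) did not, with adjusted permutation p-values of 0.195, 0.195, 0.399 and 0.484. Short native lists enter these means. In Trihelix the 3 differences above 0 came from native lists of 377, 124 and 277 peaks, and 4 were below 0. In C2H2 the 2 above 0 came from lists of 230 and 118, and 5 were below 0. Lists that refind few gene-rich sites can show little loss, so these means do not show that gene-poor sites were kept. Family membership took 43.9% of the variance (n = 171 factors in 10 families, permutation p = 0.0001, the smallest the draws can give).

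ABI5 and GBF3, bZIP factors of abscisic acid and G-box binding, were followed singly. ABI5 had 4855 native and 4378 amplified peaks, and kept 64.2% of 81 gene-poor sites (95% Wilson interval 53.3% to 73.8%, counting error only) against 99.3% of 919 gene-rich sites (98.6% to 99.7%). GBF3 had 6267 and 9767 peaks, and kept 71.6% of 88 (61.4% to 79.96%) against 89.6% of 912 (87.4% to 91.4%). The strongest native ABI5 site lay on chromosome 2 from 12108196 to 12108396 (TAIR10), between genes and 2034 bp from GATA13 (AT2G28340). The strongest native GBF3 site lay on chromosome 1 from 19759736 to 19759936, 136 bp outside AT1G53025.

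**Figure D2:**
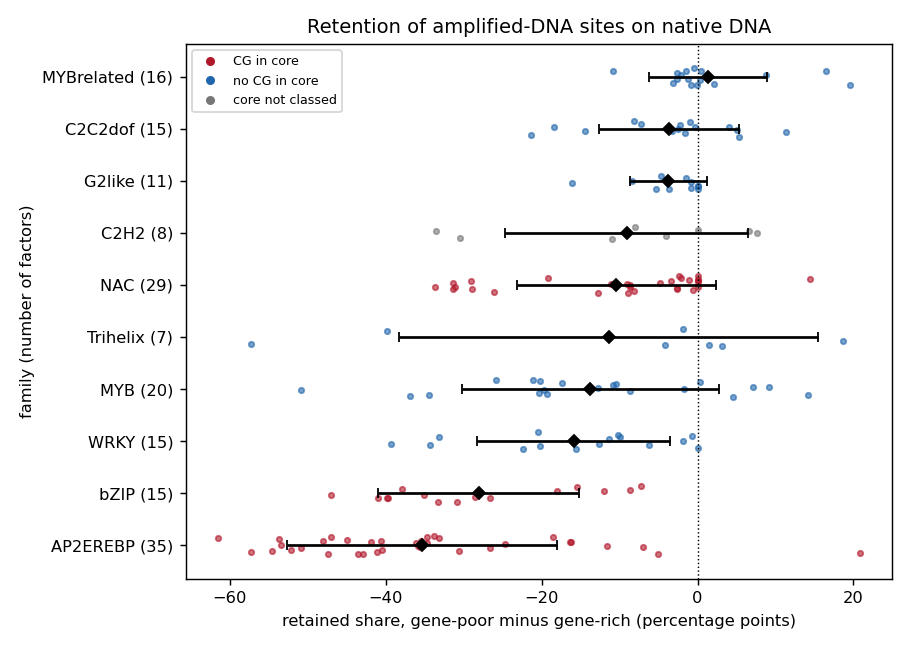
Share of the 1000 strongest amplified-DNA peaks found again on native DNA, gene-poor minus gene-rich windows in percentage points (x axis), for each factor (points) of families with 6 or more factors (y axis); diamonds and bars are the mean and SD. AP2EREBP and bZIP have the lowest means, -35.3 and -28.1, and MYBrelated the highest, 1.39.

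Gene-poor windows also held a smaller share of the strongest native peaks. Among 181 factors with full lists on both DNAs, 6.18% ± 5.81 (SD) of the 1000 strongest native peaks and 8.65% ± 4.198 of the amplified ones were gene-poor, a difference of -2.47 ± 3.88 points, below 0 in 145 factors (sign-flip permutation p = 1e-05). AP2EREBP fell from 9.21% on amplified to 3.85% on native DNA (n = 29, adjusted permutation p = 4e-05), and bZIP from 6.99% to 2.53% (n = 15, adjusted exact permutation p = 0.000163). MYB, WRKY, NAC and G2like were also lower on native DNA, by means of -4.68, -3.28, -1.79 and -1.40 points (adjusted permutation p = 0.00117, 0.000976, 4e-05 and 0.00521). C2C2dof (0.0855 points) and MYBrelated (1.22 points) did not pass (adjusted permutation p = 0.888 and 0.288).

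Families were also divided by whether their textbook core motif holds a CG, the main methylated dinucleotide. For peak number the 7 families with a CG (BZR, NAC and bHLH among them) had a mean log2 ratio of 0.24 ± 1.60 (SD) and the 17 without it -0.24 ± 1.60, a difference of 0.48 (exact permutation p = 0.545). Among pairs with full lists on both DNAs, a choice that also selects on list length, the direction turned, to -0.71 (5 families against 12, exact permutation p = 0.036). For the retention difference, a use of these classes chosen after the family means had been seen, LOBAS2 (-39.2), AP2EREBP, bHLH (-28.4), bZIP and NAC had a mean of -28.3 ± 11.05 points and the 12 families without a CG -6.82 ± 7.82, a difference of -21.5 points (exact permutation p = 0.000808). In pairs whose native list was at least as long it was -18.1 points (2 families against 9) and did not pass (exact permutation p = 0.0727).

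Lists of one family shared more of their strongest sites on average than lists of different families, with wide differences between families. Among 315 native lists, 25.3% ± 21.5 (SD) of the 1000 strongest peaks were shared by 2 lists of one family and 0.777% ± 2.67 by lists of different families, a difference of 24.5 points (permutation of family labels, p = 0.0001, the smallest the draws can give). Sharing within the family was highest in BZR, the brassinosteroid response factors (77.2%, 3 lists), and was 48.3% in HSF (4 lists), 47.9% in CPP (3 lists), 47.6% in WRKY (23 lists) and 45.4% in TCP (6 lists). It was 11.8% in MYB (29 lists), 8.87% in bHLH (5 lists) and, below the mean between families, 0.367% in ABI3VP1 (4 lists). The highest means between families were 13.3% for HB with Homeobox, 11.3% for SBP with bHLH and 10.3% for BZR with bHLH, each above the mean within Homeobox (9.81%) or bHLH.

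**Figure D3:**
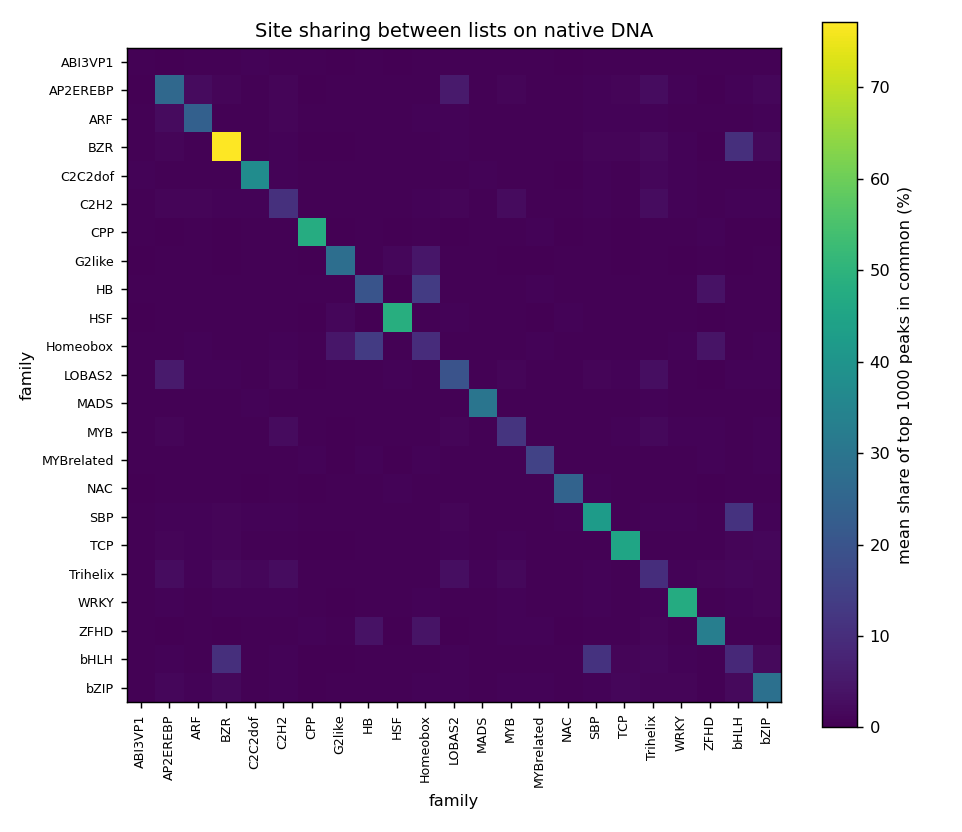
Mean share in percent (colour) of the 1000 strongest native peaks shared by 2 lists, for families with 3 or more lists on both axes. The diagonal, lists of one family, reaches 77.2% for BZR, and off it HB with Homeobox reaches 13.3%, above the 9.81% within Homeobox.

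The auxin response factors gave 4 lists on Col-0 DNA. MP (ARF5) had 26659 peaks, its maize relative ZmARF5 24762, ARF2 11654 and ARF16 483. Of the 1000 strongest MP peaks, 39.5% (95% Wilson interval 36.5% to 42.6%) were among those of ZmARF5 and 17.2% (14.99% to 19.7%) among those of ARF2, and 14.9% of the ZmARF5 peaks were among those of ARF2. Of the 483 ARF16 peaks, 1.04% (0.443% to 2.4002%) were among the strongest of MP. The strongest MP site lay inside GA2OX8 (AT4G21200), a gibberellin 2-oxidase gene, on chromosome 4 from 11304059 to 11304259. That of ZmARF5 lay in a gene-poor window on chromosome 3 from 14192189 to 14192389, 3158 bp from AT3G41762. Close by are bins found with many factors, from 14195501 to 14196000 in 172 of 530 native lists and from 14201501 to 14202000 in 328. Binding particular to ZmARF5 is therefore not shown there. Each factor has a single list here, that of MP pooled over libraries, so the differences have no replicate check. The titles mark MP and ZmARF5 as made in E. coli and ARF2 and ARF16 otherwise (tnt). Sharing and the way the protein was made can therefore not be told apart. The ARF16 list carries the motif-alone label.

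Most lists of textbook target genes had sites of the factors set against them more often than other genes. The phenylpropanoid, WRKY defence and phosphate starvation lists were set against the whole family, not against known regulators alone. Members of a family were not compared with each other on these genes. Of 22 gene lists tested, 19 exceeded random gene lists matched on how many other factors bind them, and the other 3 did not pass (permutation test with Benjamini-Hochberg adjustment over the lists). With the top 1000 peaks alone, where fewer sites enter by construction, 17 of 22 passed, and in 13 of the 19 the difference was smaller by over 1.5 times. E2FDP factors, regulators of the entry into DNA synthesis, had sites at 69.2% of 26 replication genes against 3.05% ± 2.66 (SD) of random genes (2 factors, adjusted permutation p = 0.000169). Both bound MCM2, MCM4, MCM5 and FAS1, and 4 genes were bound by neither. The MYB3R factors had sites at 78.9% of 19 mitosis genes against 11.3% ± 5.54 (3 factors, adjusted permutation p = 0.000169), among them TPX2, SYP111, HIK and CYCA1;1, with 3 genes bound by none.

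Stress and hormone lists gave large differences as well. CBF and DDF factors bound 72.6% of 14 cold-regulated genes against 10.7% ± 5.92, and all 6 had sites at COR47, ERD10, LTI30 and GolS3. Heat shock factors bound 55.1% of 23 heat shock genes against 11.3% ± 3.74, with HSFA2, HSFA7A and AT1G59860 bound by all 6 and no gene left unbound. NAC factors of mitochondrial stress bound 75% of 13 genes against 15.3% ± 7.75, including AOX1A, the alternative oxidase, BCS1, SOT12 and AT2G21640. ABI5, GBF3, ABF2 and AREB3 bound 53.4% of 22 abscisic acid response genes against 14.1% ± 6.58, and all 4 had sites at ERD10, GolS2, GEA6 and AFP3. ARF factors bound 73.7% of 33 auxin response genes against 39.8% ± 6.10, with IAA5, IAA12, SHY2 and ESR1 bound by all 3. Genes bound by none of the factors numbered 1 in the cold list, 1 in the mitochondrial list, 6 in the abscisic acid list and 4 in the auxin list. Each of these 5 lists had an adjusted permutation p of 0.000169. With the top 1000 peaks the difference fell from 39.3 to 9.79 points for the abscisic acid list (adjusted permutation p = 0.0282), from 59.7 to 26.7 for the mitochondrial, from 33.9 to 17.9 for the auxin and from 43.7 to 27.2 for the heat shock list.

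Nutrient, clock and development lists followed. The 11 G2like factors bound 78.6% of 20 phosphate starvation genes against 24.0% ± 6.18, and all 11 had sites at SPX1, SPX2, PS2 and MGD2. The 7 clock-related MYB factors bound 61.9% of 24 clock genes against 30.1% ± 6.66, with GI, FKF1, GRP7 and ELF4 bound by all 7. VND, NST and SMB factors bound 58.8% of 26 secondary wall genes against 22.1% ± 6.68, including MYB83, IRX1, XCP1 and NAC010. The 23 WRKY factors bound 43.0% of 26 defence genes against 21.2% ± 5.06, with WRKY29 and WRKY11 bound by 22 and FRK1 and FMO1 by 20. The 30 MYB factors bound 36.2% of 22 phenylpropanoid genes against 16.1% ± 2.91, led by F3H (25 factors), CCoAOMT1 (18), DFR (17) and 4CL3 (16). No phosphate starvation or phenylpropanoid gene was left unbound, and 4 clock, 3 secondary wall and 5 defence genes were. Adjusted permutation p was 0.000314 for the WRKY list and 0.000169 for the other 4. With the top 1000 peaks the difference fell from 36.7 to 5.83 points for the secondary wall list and from 21.8 to 6.57 for the WRKY list (adjusted permutation p = 0.0467 and 0.0215), from 54.6 to 26.5 for the phosphate list and from 20.09 to 11.01 for the phenylpropanoid list.

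Lists of 1 factor had no spread over factors. The EIL factor bound 38.5% of 13 ethylene response genes against 2.71% ± 4.53, among them EBF1, ETR2, ERS1 and ERS2. FUS3 bound 41.2% of 17 seed maturation genes against 4.86% ± 5.23, including OLEO1, CRU2, SESA1 and SESA2. bZIP28 bound 28.6% of 14 unfolded protein genes against 5.60% ± 6.18, namely CRT1b, PDIL1-1, SHD and P58IPK (adjusted permutation p = 0.00865, and 0.000169 for EIL and FUS3). Unbound were 8 ethylene response genes, 10 seed maturation genes and 10 unfolded protein genes. With the top 1000 peaks the difference of FUS3 fell from 36.3 to 21.9 points.

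Weaker differences were found for 4 lists. SBP factors bound 25.0% of 20 flowering genes against 12.8% ± 4.94, with AGL8 bound by all 5 and AP1 by 4 (adjusted permutation p = 0.0205). MADS factors bound 36.7% of 20 flowering genes against 20.3% ± 6.22, with AP1, SVP, SNZ and AGL15 bound by all 3 (0.0177, permutation test). The bZIP seed list had 30.4% of 17 genes against 13.0% ± 6.79, with CRA1, GEA6 and HSFA9 bound by all 6 (adjusted permutation p = 0.0182). The 3 G2like factors set against nitrate response genes bound 40.5% of 14 genes against 20.06% ± 9.27, with NIA1, WR3, UPM1 and RFNR2 bound by all 3 (adjusted permutation p = 0.0302). The number of genes bound by none was 8 in the SBP, MADS and nitrate lists and 11 in the bZIP seed list. Each lost its call under an alternative: the SBP list on amplified DNA, where the difference was larger at 15.6 points, and with the top 1000 peaks (adjusted permutation p = 0.0788 and 0.06), the MADS list on amplified DNA (6.38 points, 0.599), the nitrate list with a 2000-bp flank (14.3 points, 0.274), and the seed list with that flank and with the top 1000 peaks (0.0992 and 0.06). The amplified lists changed the factors as well as the DNA: 4 SBP factors entered against 5 on native DNA, 3 of them on both, and 1 MADS factor against 3. Leaving out 1 factor also ended the MADS call without AGL63 (10.7 points, unadjusted permutation p = 0.0906) and the nitrate call without At1g25550 (18.9 points, unadjusted permutation p = 0.053). With the top 1000 peaks the differences fell from 12.2 to 4.99 points (SBP), 16.3 to 9.07 (MADS), 17.401 to 7.54 (bZIP seed) and 20.4 to 9.77 (nitrate), and with a 2000-bp flank that of SBP rose to 24.8.

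The 3 remaining lists did not pass. BZR factors bound 11.1% of 18 brassinosteroid genes against 7.65% ± 4.67 (4 factors, adjusted permutation p = 0.585), with ROT3 bound by 3, BRI1 by 2 and 13 genes by none. TGA factors bound 12.5% of 26 defence genes against 10.7% ± 4.42 (8 factors, adjusted permutation p = 0.709), with PR1, CYP71A13 and WRKY70 bound by 6 and 19 genes by none. ERF factors bound 13.3% of 9 jasmonate and ethylene defence genes against 5.64% ± 4.96 (5 factors, adjusted permutation p = 0.119), with ORA59, TAT3, PDF1.2b and PR4 bound by 1 each and 3 genes by none. Leaving out ERF15 turned the difference to -2.72 points, and leaving out ERF105 let it pass (unadjusted permutation p = 0.0436). The ERF list did pass with a 500-bp flank, by 9.75 points (adjusted permutation p = 0.0458). It also passed on amplified DNA, by 45.7 points (adjusted permutation p = 0.00125), but there 3 factors entered against 5, with 2 on both, so the change cannot be assigned to the DNA alone.

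**Figure D4:**
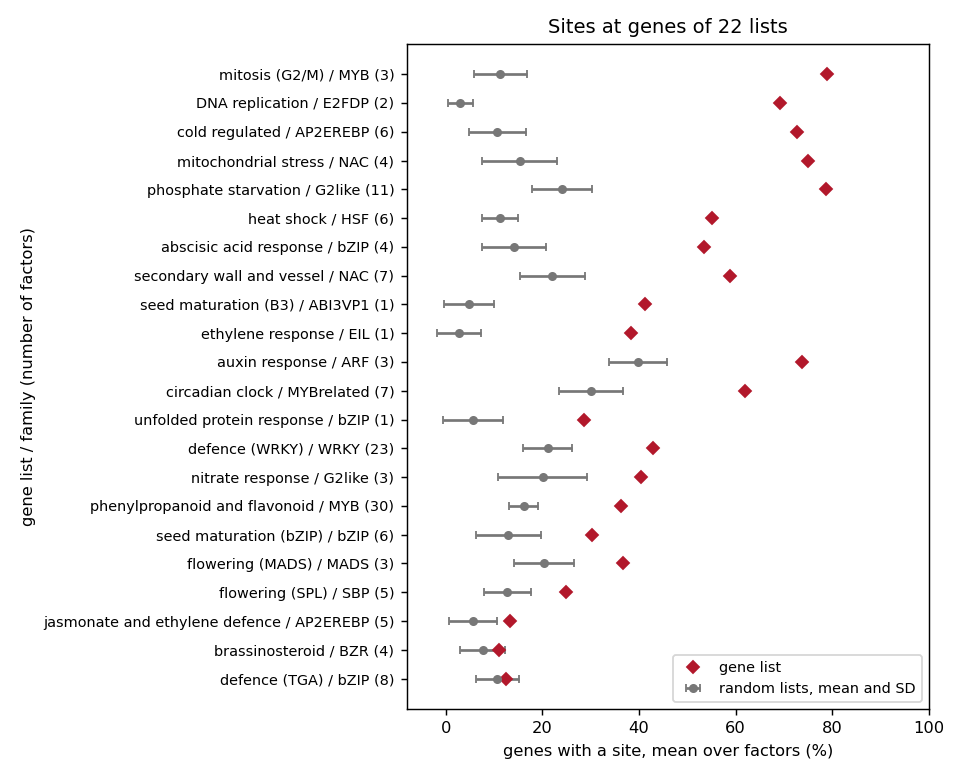
Share of listed genes with a site in percent, mean over the factors (red), and the mean and SD over matched random gene lists (grey), for each list (y axis, with the family and the number of factors). The largest difference is that of the mitosis list, 78.9% against 11.3%, and the smallest that of the TGA defence list, 12.5% against 10.7%.

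Many factors had a site at their own gene. On native DNA 96 of 349 Arabidopsis factors (27.5%) did, against 61.1 ± 6.34 (SD) when factors were exchanged between genes (permutation p = 0.0001, the smallest the draws can give). When factors were exchanged only within their family the expectation was 85.5 ± 5.32 and the difference did not pass (permutation p = 0.0588), though it did with a 500-bp flank (an excess of 13.6 factors against 10.5, permutation p = 0.0061). On amplified DNA, with 219 factors, the excess within families was 1.45 factors (permutation p = 0.827), and over all exchanges 15.6 against 34.9 on native DNA (permutation p = 0.0064). Own-gene sites were found for 6 of 6 ZFHD, 6 of 8 HB, 8 of 11 G2like and 12 of 20 C2C2dof factors, and for 0 of 8 TCP, 0 of 6 HSF and 3 of 53 AP2EREBP factors. No expected count per family was drawn. Over all native lists the median length was 20604 peaks in ZFHD, 9298.5 in HB, 9128 in G2like and 13861 in C2C2dof. It was 995 in TCP, 859.5 in HSF and 2370 in AP2EREBP, so these counts do not show self-binding apart from list length.

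Genes of assayed factors were bound by more factors than other genes. The median was 59 of 350 lists at 533 factor genes and 53.1 ± 1.202 (SD) in sets of other genes matched on distance to their neighbours (permutation p = 0.0001). The excess of 5.85 lists was 1.77 with the top 1000 peaks (permutation p = 0.0003) and 8.71 with a 2000-bp flank (permutation p = 0.0001). The genes with a site in the most native lists were AT2G01023 (523 of 530 lists) and AT2G08986 (315), followed by AT5G10340 (195), AT2G01008 (186), AT1G73875, AT2G07629 and AT2G07687 (174 each), AT2G07638 (170), GBF2 (169) and AT3G18680 (159). For most of these genes the count came mainly from 500-bp bins present in over 20% of the lists on either DNA. Without those bins AT2G01023 and AT2G07687 had a site in 1 list each, AT2G08986 in 42, AT5G10340 in 18, AT2G01008 in 15, AT2G07629 in 59 and AT2G07638 in 10. The counts of AT1G73875, GBF2 and AT3G18680 were unchanged.

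On average over the assayed lists, peaks lay in the flanks of genes more often than random positions. Within 1000 bp outside a protein-coding gene lay 25.0% ± 11.8 (SD, n = 350 lists) of native peaks and 20.4% of the genome, a difference of 4.56 points (sign-flip permutation p = 1e-05), and 225 of 350 lists exceeded the genome. Families went both ways. The p-value takes the lists as independent, though lists of a family can be alike, and no test over families was run. The mean therefore depends on how many factors of each family were assayed. Among families with 6 or more lists, ZFHD (47.6% ± 2.28, n = 6), HB (42.2% ± 5.87, n = 8) and Homeobox (39.4% ± 8.31, n = 7) had the highest shares. LOBAS2 (7.70% ± 2.96, n = 6), AP2EREBP (10.1% ± 6.62, n = 53) and HSF (12.7% ± 1.88, n = 6) had the lowest. Gene strand was not used, so both flanks count. The share inside genes, which cover 54.1% of the genome, was not tested. In the check of the gene table, 30.8% to 70.7% of the strongest peaks of a segment lay inside genes. A preference for flanks over gene bodies is therefore not shown.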

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

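The reverse control of the mean loss, the share of variance between families, the use of the CG classes on retention and the weighing against methylation were chosen after the retention values had been seen; rank matching, the restriction by list length and the 3 tests of the family difference were added later but stated before their results.

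Families differed in the loss of gene-poor sites on native DNA, with 43.9% of the variance between families, and families with a CG in their core lay -21.5 percentage points from the others. Weaker peaks in gene-poor windows are argued against as the whole cause: with ranks matched, 45.8% of the variance lay between families (n = 171, permutation p = 0.0001) and the class difference was -21.2 points (exact permutation p = 0.00097). Shorter native lists are argued against as the whole cause of the difference between AP2EREBP, C2C2dof, NAC and WRKY only. Among these, 58.1% of the variance lay between families in pairs whose native list was at least as long (33 factors of 4 families, permutation p = 0.0001). The other families, bZIP among them, had too few such pairs to enter. List length therefore stays open for them, and the 58.1% cannot be set against the 43.9%. It also stays open for the classes, where 2 families against 9 gave -18.1 points (exact permutation p = 0.0727). Poor recovery in both directions stays open. The difference less its reverse, native sites sought in amplified lists, had 36.2% of its variance between families (n = 157, permutation p = 0.0001). Between classes it was -24.2 points (exact permutation p = 0.0011). The reverse always searched a full amplified list, while native lists could be short, so the directions were not tested alike. Methylation of CG cores on native DNA is a candidate explanation that would give a class difference in this direction (-21.5). WRKY (-15.9) and SBP (-21.3) also lost gene-poor sites and are classed as without a CG. That class rests on textbook cores, and motifs at the peaks were not examined, so these families do not settle the question. Methylation was not measured here, and amplification itself may change which gene-poor fragments are present.

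The mean loss over all factors was put to the same tests. It was -15.7 points with ranks matched (n = 216, sign-flip permutation p = 1e-05) and -13.9 points in the 64 pairs whose native list was at least as long (permutation p = 1e-05). In the reverse direction the difference was -3.70 points, so that forward minus reverse was -11.3 points (n = 201, permutation p = 1e-05). The reverse searched full amplified lists only, so it cannot decide on poor recovery in both directions. Neither peak rank nor list length accounts for the whole mean loss.

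The list of ZmARF5 on maize DNA, which entered no comparison, held 228514 peaks on 10 chromosomes, and no maize control list was set beside it. Among 18 sets of 4 to 10 factors of a family, none had a factor far from the rest by the gap-to-range test, which flags about 1 in 20 by chance.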

How the results depend on the processing

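Alternatives that leave out recurrent sites, match ranks, compare list lengths, subtract the reverse, leave out titles naming another DNA, weight retention by family, or leave out a family or factor in turn were chosen after seeing the data, as were the shares of variance between families and the CG class test of retention, which lost its call where the native list was at least as long (-18.1 points, fewer families entering). No paired analysis was possible by replicate letter because each factor has 1 list per DNA; pairs are by factor throughout. Of 49 alternatives fixed at the outset, 12 were not run, for want of genome sequence or transposable elements. Among alternatives of the main results 118 kept direction and side of the threshold, 7 lost the call, 1 gained it and 1 turned direction. Many of these left out 1 family in turn, 39 for the peak number ratio and 31 for retention, which often removes few factors. Retention was -11.3 points less its reverse, and stayed between -16.8 and -11.9 points over its other settings. It was between -16.4 and -11.2 when each family was left out. The peak number ratio lost its call with the stricter q-value (-0.055) and with family means (-0.24), and leaving out each family gave -0.39 to -0.22; the cause was not tested. The CG class difference in peak number turned to -0.71 with full lists only, where fewer families entered and list length was selected on. Own-gene sites within families passed with a 500-bp flank (an excess of 13.6 factors, permutation p = 0.0061) and not otherwise (1.45 on amplified DNA). The TGA defence difference turned to -1.94 (500 bp), -3.91 (2000 bp), -0.569 (top 1000 peaks) and -1.30 points (amplified DNA), and that of the jasmonate list to -2.72 without ERF15, none past the threshold; leaving out each of its factors gave -2.72 to 11.1 points, past the threshold (unadjusted permutation p = 0.0436) without ERF105. The number of lists above random was 17 to 20 of 22 on native DNA and 15 of 18 on amplified DNA, the aluminium list among the 18. MADS flowering lost its call without AGL63 (10.7 points, unadjusted permutation p = 0.0906) and nitrate response without At1g25550 (18.9 points, unadjusted permutation p = 0.053). The jasmonate list passed on amplified DNA, with other factors (45.7 points, adjusted permutation p = 0.00125), and with a 500-bp flank (9.75 points, 0.0458). With the top 1000 peaks 13 of 19 differences shrank by over 1.5 times, as fewer sites enter. Depth per list is unknown, so short lists do not show absent binding.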

Other observations

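The test of recurrent sites was written before its result was seen, after the sites themselves had been noticed. The recurrent sites belong to no comparison above, and the aluminium list entered only the count of gene lists on amplified DNA.

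STOP1, a zinc finger factor of acid and aluminium tolerance, had a full list only on amplified DNA. Its listed target genes exceeded matched random genes by 97.5 percentage points (1 factor, adjusted permutation p = 0.00018). This rests on 1 library with 1356 peaks, and the native list of STOP1 held 118 peaks with the motif-alone label. The number of listed genes is not given here, so the size of the difference is not set against other lists.

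A few places were occupied in most lists. On native DNA 8 bins of 500 bp were present in over 50% of the 530 lists, the first on chromosome 2 from 10001 to 10500 in 508 lists of 54 families, and the next on chromosome 3 from 13591501 to 13592000 in 499. Enrichment that does not depend on the factor is a candidate explanation: lists labelled with a motif alone, which are short, held these bins in 80.2% of cases and full lists in 74.96%, a mean difference of 5.24 points. The bin on chromosome 2 from 9501 to 10000 went the other way, at 42.2% against 79.7%. All 8 bins were picked for being in over 50% of these same lists, motif-alone lists among them. Similar shares under both labels are therefore partly built in, most of all for the bins in 508 and 499 lists. No biological explanation was tested, and copy number could not be examined without sequence.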
